A study of Arabidopsis thaliana with 17 samples.

How the data were processed

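Whole plants of Arabidopsis thaliana were sampled at 25 days, after growth in 12 h of light and 12 h of dark at 22 °C, 60% humidity and 180 µmol m-2 s-1, per the labels' protocols. Libraries of mRNA were made with a NEBNext Ultra kit. Per the submitters' processing notes, reads were handled with fastp, HISAT2, featureCounts and DESeq2 against TAIR10; the notes give no versions, parameters, order or strand setting. The authors deposited 1 table of FPKM for 32833 genes in 17 libraries, with each gene's position and length, and no count table was analysed here. Gene names came from this table and the TAIR10.1 annotation, in which 32548 of the identifiers were found and 99.95% of these had the same start and end.

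FPKM multiplied by gene length was a whole multiple of a single step in each library for 100% of values, within 0.01 of a whole number. The steps gave the reads per gene, and the totals had a median of 17455230. A gene of 1000 bases needed an FPKM of 0.139 to 0.254, depending on the library, to reach 3 reads. Depth therefore bounds what can be said of genes with an FPKM near or under 1; intervals and floors from reads cover counting error only. Recovered reads served for depth and for a single alternative test.

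Libraries were grouped by the strain in the labels. These gave 10 groups, 5 of them with 1 library, and 7 residual degrees of freedom. The libraries of replicate 3 carry allele number 3 in every group except Col-0 and flk-5. The deposited sample sheet gives flk-3, acd6-3 and acd6-3flk-3 the codes of flk-1, acd6-1 and acd6-1flk-1 and does not list acd6-3flk-5. It also lists a replicate 2 under the code of acd6-1flk-5, for which no library was analysed here. The libraries with allele number 3 were kept as groups of their own, and counting them with number 1 was an alternative. For Col-0 replicates 2 and 3 and flk-1 replicate 1 a further genotype field disagrees with the title and strain, which were followed.

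The main test was limma with a mean-variance trend on log2(FPKM + 1), for 18328 genes with an FPKM of at least 1 in at least 2 libraries. A model of 10 group means was fitted to all 17 libraries, so that groups of 1 library borrowed the spread of the others. Tests were two-sided, and p was adjusted by Benjamini and Hochberg's method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low FPKM; values after ± are standard errors unless named SD. The 8 tested comparisons were flk-1, flk-5, acd6-1 and acd6-1flk-1 against Col-0, acd6-1flk-1 and acd6-1flk-5 against acd6-1, flk-1 against flk-5, and the interaction of flk-1 with acd6-1. The test was tried on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among the 18328. The changed genes were drawn only from those with a mean FPKM of at least 5, so recovery was not tried at lower FPKM. The comparisons, test, thresholds, alternatives, gene lists and the rule for named genes were chosen before the data were examined. The design had foreseen a count test in case of a count table, and the clause did not apply to FPKM.

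A total of 17 gene lists were fixed: salicylic acid synthesis and signalling, pathogenesis-related and defence output, pattern-triggered immunity, jasmonate and ethylene response, floral repressors, floral promoters, autonomous pathway, flower organ markers, root markers, photosynthesis, leaf senescence, circadian clock, endoplasmic reticulum chaperones, heat shock proteins, cold and abscisic acid response, and aliphatic and indole glucosinolate synthesis. They hold 285 entries, of which 282 matched by symbol and 3 by identifier. Lists were tested with camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the residuals, adjusted over the 17 lists of a comparison. In every comparison, the list calls at the preset correlation were lost with the estimated correlation. The lists were also tested with fry, which asks whether a list's genes changed at all, not whether they changed more than other genes. For the salicylic acid, pathogenesis-related and pattern-triggered immunity lists the fry adjusted p was 0.00053, 0.00066 and 2.1e-06 in acd6-1 against Col-0. It was 0.16, 0.24 and 1.4e-05 in acd6-1flk-1 against acd6-1, and 0.14, 0.18 and 0.0075 in flk-5 against Col-0. Members were counted by their p adjusted over all genes tested, and again adjusted over the list alone.

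Genes were named by rule. FLK, ACD6, FLC, PR1 and ICS1 were named in every comparison. To these were added the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap between groups and whose mean FPKM over all libraries was at least 2. From each list with a call, the 4 members with the smallest adjusted p were added, and from a list without a call up to 2 members with the largest change. Examples in the text are taken from these.

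The alternatives were a pseudocount of 0.1, no filter, an FPKM of at least 5, scaling by median ratios, quantile normalization, fits without trend or with robust hyperparameters, the replicate number as a block, allele number 3 counted with number 1 with and without that block, a minimum change of 1 on the log2 scale, and leaving out each library in turn. A fit with voom on the recovered reads was added after the values were seen to be whole multiples. Shared calls of 2 comparisons were set against independent lists and against groups simulated without change around the shared controls, 100 times. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.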

Results

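The mRNA of 25-day-old Arabidopsis thaliana plants, grown under 12 h of light and 12 h of dark at 22 °C, was sequenced in 17 libraries. The plants were wild type (Col-0), mutants of FLK, mutants of ACD6, or carried a mutation in both genes. FLK encodes an RNA-binding protein with KH domains that promotes flowering, and ACD6 encodes a membrane protein with ankyrin repeats that promotes defence. The acd6-1 allele is a gain-of-function allele that keeps defence switched on and dwarfs the plant. The labels gave 3 libraries each for Col-0 and flk-5, 2 each for flk-1, acd6-1 and acd6-1flk-1, and 1 each for acd6-1flk-5, flk-3, acd6-3, acd6-3flk-3 and acd6-3flk-5. Groups of 1 library have no replicate. The libraries held between 15342054 and 21333625 reads assigned to genes, recovered from the deposited FPKM values, and between 20477 and 22133 genes were detected in each. Library type explained most of the variance among samples: the first principal component, which held 60.1% of it, set the libraries with an acd6 mutation apart from the others.

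FLK (AT3G04610; chromosome 3, 1250553 to 1254984, minus strand, TAIR10) was examined first, since it is the targeted gene. Its mRNA stood at 10.1, 9.16 and 9.55 FPKM in Col-0 replicates 1, 2 and 3. It was 0.591 and 1.26 FPKM in flk-1 replicates 1 and 2 and 1.32 FPKM in the flk-3 library. In acd6-1flk-1 replicates 1 and 2 it was 1.15 and 1.39 FPKM, and in acd6-3flk-3 it was 1.63 FPKM. In flk-5 replicates 1, 2 and 3 it was 10.8, 11.7 and 10.6 FPKM, in acd6-1flk-5 it was 11.6 FPKM and in acd6-3flk-5 it was 10.7 FPKM, so its level does not check the labels of the flk-5 libraries. It was 15.5 and 15.2 FPKM in acd6-1 replicates 1 and 2 and 12.5 FPKM in acd6-3. FLC (AT5G10140; chromosome 5, 3173382 to 3179448, minus strand), the MADS-box repressor of flowering that FLK keeps low, did separate every library with a flk mutation, at 15.8 to 35.5 FPKM, from every library without one, at 0.741 to 1.37 FPKM. Use of strand in counting was not stated, so reads from antisense RNA at FLC cannot be told apart from those of its mRNA.

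**Figure D1:**
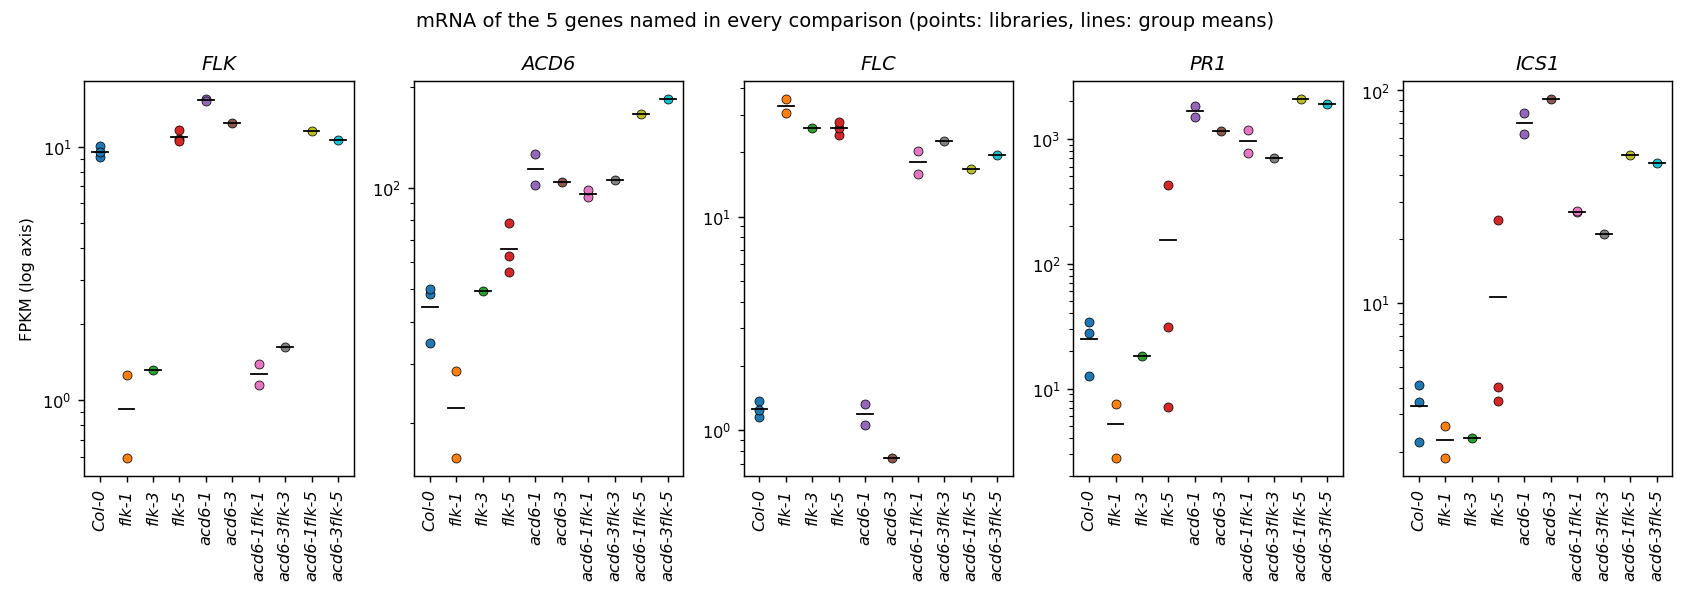
FPKM of FLK, ACD6, FLC, PR1 and ICS1 in each of the 17 libraries on log axes, with points for libraries and lines for group means. FLK was at or below 1.63 FPKM in the flk-1 and flk-3 libraries and their combinations with acd6 and at or above 9.16 FPKM in all others, and PR1 ranged from 7.11 to 426 FPKM among the 3 flk-5 libraries.

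The comparison of flk-1 with Col-0 asked which mRNAs change when FLK mRNA is lost in plants without the acd6-1 allele. FLC rose from 1.25 ± 0.105 FPKM in Col-0 (SD, n = 3) to 33.0 ± 3.5 FPKM in flk-1 (SD, n = 2). This was a log2 fold change of 3.91 ± 0.15 (SE; adjusted p = 1.1e-07). FUL, a MADS-box gene of the floral transition, fell by 2.51 ± 0.21 on the log2 scale (adjusted p = 0.00035), and SOC1, a flowering integrator that FLC represses, fell by 1.57 ± 0.24 (adjusted p = 0.012, and 0.079 without flk-1 replicate 1). RPP2C, a gene of the acidic ribosomal protein family, fell by 2.93 ± 0.25 (adjusted p = 0.00035). PR1, a marker of salicylic acid defence, stood at 5.17 ± 3.39 FPKM in flk-1 (SD, n = 2) and at 24.9 ± 11 FPKM in Col-0 (SD, n = 3), a difference that did not pass (adjusted p = 0.32).

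Among the fixed gene lists, 1 of 9 floral promoters rose in flk-1 and 3 fell. Both measured flower organ markers fell. PI and SEP3 had 1 and 2 reads in all flk-1 libraries together, against 1.27 and 1.47 FPKM in Col-0. Their adjusted p was 0.034 and 0.039, and 0.11 and 0.13 without flk-1 replicate 1. Of 14 cold and abscisic acid genes, 1 rose and none fell, and 10 rose when adjusted over the list alone. Part of these genes were lower in Col-0 replicate 1 than in the other Col-0 libraries, as ERD10 at 34.4 against 110 and 111 FPKM, with 164 and 225 FPKM in flk-1. The list's median was 0.80 on the log2 scale (camera adjusted p = 4.75e-07, and adjusted p = 0.346 with an estimated correlation). COR15A, which encodes a chloroplast protein protective against freezing, led it at 1.41 ± 0.25 (adjusted p = 0.028, and 0.12 without flk-1 replicate 2). Of 33 jasmonate and ethylene genes 3 rose, and 4 when adjusted over the list alone. Among them was JAZ5, a repressor of jasmonate signalling, at 1.12 ± 0.16 (adjusted p = 0.012, and 0.077 without flk-1 replicate 2). The camera call of that list (adjusted p = 0.00739, and adjusted p = 0.442 with an estimated correlation) was lost without Col-0 replicate 3 (0.148) or flk-1 replicate 2 (0.0805). None of 26 pathogenesis-related genes passed over all genes tested, and 3 fell when adjusted over the list alone. Their median of -0.56 passed camera (adjusted p = 0.00352, and adjusted p = 0.742 with an estimated correlation) but not without flk-1 replicate 1 (0.0707). None of the 2 root markers, 30 photosynthesis, 13 endoplasmic reticulum chaperone, 5 heat shock and 9 aliphatic glucosinolate genes passed. None of 27 salicylic acid genes did either, also when adjusted over the list alone. Their median of -0.33 passed camera (adjusted p = 0.0411, and adjusted p = 0.837 with an estimated correlation), but not without flk-1 replicate 1 (0.497), Col-0 replicate 2 (0.115) or Col-0 replicate 3 (0.0724).

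With limma, 368 of 18328 genes passed an adjusted p of 0.05, 163 higher and 205 lower in flk-1, and 127 of them changed at least 2-fold. On simulated data the fit recovered 72% of genes changed by 1 and 97% of those changed by 2 on the log2 scale. The simulated changes were all in genes with a mean FPKM of at least 5. The count hung on single libraries: it was 33 without flk-1 replicate 1, 36 without flk-1 replicate 2, 223 without Col-0 replicate 1, 71 without Col-0 replicate 2 and 1453 without Col-0 replicate 3. FLK, FLC, FUL and RPP2C kept their call in each of these fits, and the other 23 of the 27 called genes named by rule did not. The number of called genes was 184 with no filter on low values and 113 with the replicate number as a block. It was 2114 when the libraries labelled with allele number 3 were counted with those of number 1.

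The comparison of flk-5 with Col-0 asked the same of an allele whose FLK mRNA was not reduced (log2 fold change 0.18 ± 0.14, adjusted p = 0.42). FLC rose to 26.0 ± 1.84 FPKM (SD, n = 3), a log2 fold change of 3.58 ± 0.13 (SE; adjusted p = 8.5e-08). FUL fell by 2.12 ± 0.19 (adjusted p = 0.00012) and SOC1 by 1.21 ± 0.21 (adjusted p = 0.0047). WRKY33, a transcription factor of camalexin synthesis, rose by 2.53 ± 0.30 (adjusted p = 0.0006), CYP71A13, an enzyme of camalexin synthesis, by 2.62 ± 0.55 (adjusted p = 0.0099), and RBOHD, the oxidase behind the oxidative burst, by 1.49 ± 0.14 (adjusted p = 0.00017). QQS, an orphan gene tied to carbon and nitrogen allocation, rose by 2.86 ± 0.17 (adjusted p = 5.7e-06) and PI4KG3, of the phosphatidylinositol 4-kinase gamma family, by 4.0 ± 0.21 (adjusted p = 2.5e-06). XTH15, a cell wall xyloglucan enzyme gene, fell by 2.65 ± 0.30 (adjusted p = 0.00048), and MIOX2, of inositol breakdown, by 2.38 ± 0.20 (adjusted p = 0.0001).

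Of 33 jasmonate and ethylene genes, 14 rose and 3 fell in flk-5 (20 and 4 when adjusted over the list alone; camera adjusted p = 2.33e-06, and adjusted p = 0.361 with an estimated correlation). They included the lipoxygenase gene LOX4 (2.27 ± 0.19) and JAZ5 (1.83 ± 0.15). Of 22 pattern-triggered immunity genes 8 rose and none fell (camera adjusted p = 0.000112, and adjusted p = 0.361 with an estimated correlation). Of 27 salicylic acid genes 8 rose and none fell, with a camera adjusted p of 0.000112 (adjusted p = 0.471 with an estimated correlation). They included WRKY54 (1.72 ± 0.25) and CBP60G (1.33 ± 0.26), a transcription factor that turns on salicylic acid synthesis. Adjusted over the list alone, 8 salicylic acid genes rose, and 9 pattern-triggered immunity genes rose and 1 fell. Of 26 pathogenesis-related genes 3 rose and none fell (camera adjusted p = 0.00023, and adjusted p = 0.471 with an estimated correlation). The medians of the salicylic acid and pathogenesis-related lists, 0.78 and 0.74, rested largely on flk-5 replicate 3: they were 0.063 and 0.18 without it, though camera still passed, and without replicate 2 the former was 1.26. Against the Col-0 library of the same number, replicate 3 alone had medians of 2.17 and 2.34. PR1 and ICS1, the main enzyme gene of salicylic acid synthesis, did not pass, and replicate 3 stood apart here too. PR1 was 31.3 and 7.11 FPKM in flk-5 replicates 1 and 2 and 426 FPKM in replicate 3, and ICS1 was 4.02, 3.48 and 24.7 FPKM. Of 14 cold and abscisic acid genes 5 rose, of 8 indole glucosinolate genes 2 rose and of 9 aliphatic glucosinolate genes 2 rose, with none falling in any of these lists. Of the floral promoters 1 rose and 4 fell, and of 14 floral repressors 3 rose and 2 fell. Of 30 photosynthesis genes 1 rose and 2 fell, and their median of -0.23 turned to 0.16 under quantile normalization, where camera called the list higher (adjusted p = 0.0302).

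The flk-5 fit called 2992 of 18328 genes, 1381 higher and 1611 lower, of which 539 changed at least 2-fold, and recovered 84% and 99% of simulated changes of 1 and 2 on the log2 scale. The count was 1218 without flk-5 replicate 1, 1216 without flk-5 replicate 3, and 4506 when the libraries of allele number 3 were counted with number 1. Of the 55 called genes named by rule, 23 lost their call in at least 1 fit with a library left out.

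The flk-1 and flk-5 lists of called genes were then set against each other, since both alleles were measured against the same Col-0 libraries. Among called genes 127 were higher and 161 lower in both, and 2 went opposite ways. Independent lists of these sizes would share 12.3 higher and 18.0 lower genes. Unchanged groups simulated against the shared controls gave 0.01 shared calls. That value is low by construction, because few genes are called where none is changed, so it gives no baseline for the shared count. The simulated noise was also drawn for each gene on its own. Over all genes 75.3% went the same way, against a simulated 64.8%. The log2 fold changes correlated across genes at 0.642, where shared controls alone gave 0.448, and their covariance was 0.111 against a simulated 0.0200. Genes are not independent replicates, and Col-0 has too few libraries to be split, so part of the excess may come from the shared controls. The shared count of 288 changed to 31 without flk-1 replicate 1, 25 without flk-1 replicate 2, 182 without Col-0 replicate 1, 60 without Col-0 replicate 2, 1164 without Col-0 replicate 3, and 69, 96 and 128 without flk-5 replicates 1, 2 and 3. It was 153 with no filter and 1558 with the libraries of allele number 3 counted with number 1. Compared directly, flk-1 and flk-5 differed in 88 genes, 40 higher and 48 lower in flk-1. FLK was lower in flk-1 by -2.66 ± 0.16 (adjusted p = 8.7e-06), QQS by -3.49 ± 0.19 (adjusted p = 6.2e-06) and PI4KG3 by -4.07 ± 0.24 (adjusted p = 7.6e-06), whereas PAR2, a transcriptional cofactor of the shade response, was higher by 2.01 ± 0.18 (adjusted p = 0.00051). FLC did not differ detectably (0.33 ± 0.15, adjusted p = 0.35). ACD6 was lower in flk-1 by -1.58 ± 0.24 (adjusted p = 0.019), but not past the threshold without flk-1 replicate 1 (0.22) or flk-5 replicate 3 (0.056). In the defence output list 3 of 26 genes were lower in flk-1 over all genes tested and 22 when adjusted over the list alone (median -1.24; camera adjusted p = 2.77e-17, and adjusted p = 0.187 with an estimated correlation); in the salicylic acid list these counts were 1 and 16 of 27 (median -1.21). Without flk-5 replicate 3 the medians of these lists were -0.64 and -0.55. The number of genes between the alleles was 8 without flk-1 replicate 1, 134 without flk-1 replicate 2, 58 without flk-5 replicate 1, 217 without flk-5 replicate 2 and 36 without flk-5 replicate 3. It was 17 with no filter, also 17 with the replicate number as a block, and 50 without the mean-variance trend. With voom on recovered reads it was 135, and with the libraries of allele number 3 counted with number 1 it was 563.

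The comparison of acd6-1 with Col-0 gave the state of defence on which the flk mutations were then tested. PR1 rose from 24.9 ± 11 FPKM in Col-0 (SD, n = 3) to 1666 ± 240 FPKM in acd6-1 (SD, n = 2), a log2 fold change of 6.11 ± 1.15 (SE; adjusted p = 0.0009). ICS1 rose from 3.27 ± 0.960 to 70.4 ± 11.4 FPKM (SD, n = 3 and 2), a log2 fold change of 4.08 ± 0.56 (SE; adjusted p = 9.2e-05). ACD6 itself (AT4G14400; chromosome 4, 8294165 to 8299195) rose by 1.36 ± 0.24 (adjusted p = 0.00055), and FLK by 0.63 ± 0.16 (adjusted p = 0.0066), while FLC did not pass (-0.04 ± 0.15, adjusted p = 0.82). The genes with the largest rise included WRKY46, a defence transcription factor (6.94 ± 0.43, adjusted p = 2.1e-07), LOX4 (6.61 ± 0.21, adjusted p = 4.8e-09) and MYB15, a regulator of lignin defence (6.32 ± 0.30, adjusted p = 4e-08). Among the genes with the largest falls were XTH15 (-5.13 ± 0.33, adjusted p = 3e-07), XTH6 (-4.69 ± 0.19, adjusted p = 2.2e-08) and the gibberellin-regulated GASA1 (-4.36 ± 0.33, adjusted p = 7.8e-07), together with COR15A (-4.22 ± 0.25, adjusted p = 1.9e-07).

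All 26 pathogenesis-related genes rose in acd6-1, as did 25 of 27 salicylic acid genes, the other 2 falling, and 21 of 22 pattern-triggered immunity genes, the other falling. Adjusted over the list alone these counts were unchanged. The median rises were 3.31, 2.94 and 2.2 on the log2 scale, with camera adjusted p of 8.43e-11, 3.86e-09 and 4.47e-11 (adjusted p = 0.438, 0.438 and 0.310 with an estimated correlation). Examples were EDS1, a hub of immune signalling (3.31 ± 0.27), the negative salicylic acid receptor gene NPR3 (2.79 ± 0.16), RBOHD (4.36 ± 0.16) and LYK5, a chitin receptor gene (4.38 ± 0.22). Of 13 endoplasmic reticulum chaperone genes 12 rose (camera adjusted p = 8.71e-05, and adjusted p = 0.438 with an estimated correlation), with the calreticulin gene CRT3 at 2.01 ± 0.21, and all 5 heat shock genes rose. Of 8 indole glucosinolate genes 6 rose, led by CYP79B2 (2.71 ± 0.19), which makes indole-3-acetaldoxime, and MYB51 (2.63 ± 0.23), the list's main regulator. Of 33 jasmonate and ethylene genes 15 rose and 6 fell, of 14 cold and abscisic acid genes 4 rose and 5 fell, and of 14 autonomous pathway genes 8 rose and 1 fell. Of 12 leaf senescence genes 5 rose and 2 fell, of 9 clock genes 3 rose and 2 fell, and of 14 floral repressors 2 rose and 2 fell. Of 30 photosynthesis genes 19 fell and none rose, with RBCS2B, a small subunit gene of Rubisco, at -1.83 ± 0.20. The list's median of -0.77 (camera adjusted p = 1.32e-05, and adjusted p = 0.477 with an estimated correlation) became -0.035 under quantile normalization, which ended the call (adjusted p = 0.985). These genes took 8.61% and 11.6% of reads in the acd6-1 libraries and 15.2% to 19.0% in Col-0, where replicate 1 stood apart from the 15.2% and 15.3% of the others. Copies of Rubisco and light-harvesting genes are near-identical, so the split of reads among them is uncertain.

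In all, 9666 of 18328 genes passed, 4934 higher and 4732 lower in acd6-1, and 4086 of them changed at least 2-fold. The fit recovered 74% and 100% of simulated changes of 1 and 2 on the log2 scale.

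**Figure D2:**
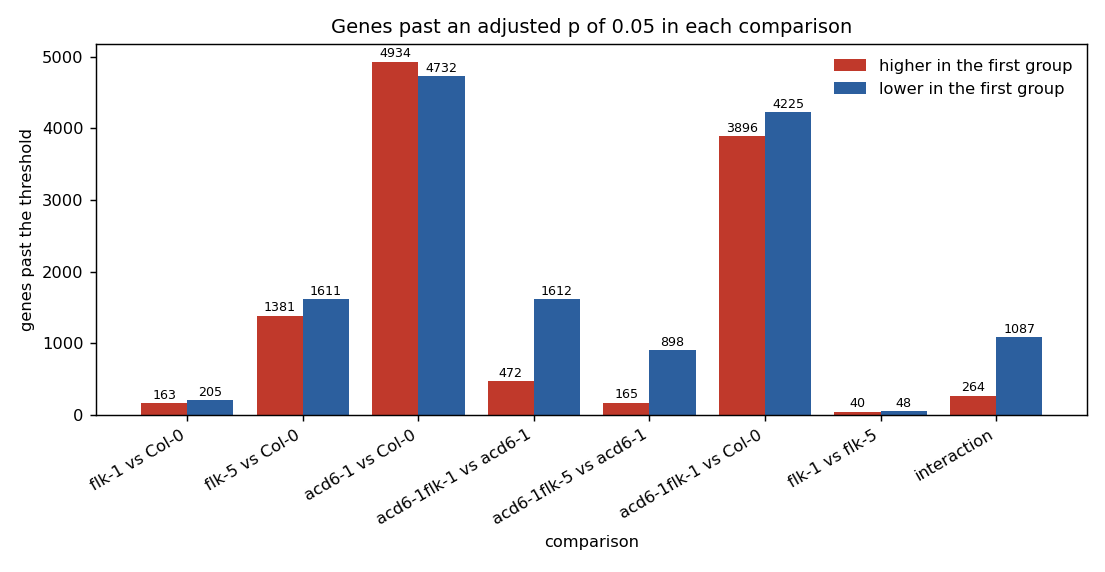
Number of genes past an adjusted p of 0.05 in each of the 8 tested comparisons, higher (red) and lower (blue) in the group named first, out of 18328 genes. Losses exceeded gains in acd6-1flk-1 (472 higher, 1612 lower) and acd6-1flk-5 (165 higher, 898 lower) against acd6-1.

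The comparison of acd6-1flk-1 with acd6-1 asked how loss of FLK changes the mRNA of plants with defence switched on. Among the genes with the largest falls were ERF109, a stress-induced transcription factor gene (-5.79 ± 0.33, adjusted p = 2.1e-07), MYB15 (-5.40 ± 0.33, adjusted p = 3.4e-07), LOX4 (-5.37 ± 0.23, adjusted p = 5.7e-08) and DREB1F (-5.34 ± 0.34, adjusted p = 4.9e-07). FLK fell by 2.85 ± 0.18 (adjusted p = 3.9e-07) and FLC rose by 3.11 ± 0.16 (adjusted p = 1.3e-07), to 18.1 ± 3.23 FPKM (SD, n = 2). PR1 was 967 ± 284 FPKM in acd6-1flk-1 and 1666 ± 240 FPKM in acd6-1 (SD, n = 2 each), a log2 difference of -0.81 ± 1.26 that did not pass (adjusted p = 0.81). Neither ICS1 (27.0 FPKM against 70.4 FPKM; -1.34 ± 0.61, adjusted p = 0.24) nor ACD6 (-0.24 ± 0.26, adjusted p = 0.72) passed. For ICS1 the libraries of each group lay close together (26.9 and 27.0 FPKM against 78.5 and 62.3 FPKM), and the standard error pools the spread of all groups, that of 3.48 to 24.7 FPKM in flk-5 included, so the missed threshold does not show that ICS1 was unchanged. SAUR24, of the auxin-induced growth genes, rose by 2.69 ± 0.34 (adjusted p = 0.00016).

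Of 22 pattern-triggered immunity genes 17 fell and none rose (18 when adjusted over the list alone), with a median of -1.99 (camera adjusted p = 9.47e-22, and adjusted p = 0.0587 with an estimated correlation). They included PHI1 (-4.44 ± 0.22), RBOHD (-3.53 ± 0.17), WRKY22, a transcription factor gene induced by flagellin (-3.06 ± 0.21), and PEPR1, a receptor gene for danger peptides (-2.61 ± 0.18). Of 26 pathogenesis-related genes 3 fell and none rose, and of 27 salicylic acid genes 7 fell and none rose (8 when adjusted over the list alone). Among the latter were NPR3 at -2.25 ± 0.18, NDR1, which acts in resistance through some immune receptors, at -2.22 ± 0.22 and CBP60G at -2.43 ± 0.32. Camera adjusted p was 0.00157 and 0.000177 for the pathogenesis-related and salicylic acid lists, and adjusted p = 0.693 with an estimated correlation for both. Their medians were -0.77 and -0.56. Standard errors were 1.26 for PR1 and 0.61 for ICS1, against a median of 0.21 over all genes. A missed threshold for such genes therefore does not show that they were unchanged, and the counts do not rank these lists against that of pattern-triggered immunity. Of 33 jasmonate and ethylene genes 14 fell and 1 rose (camera adjusted p = 2.84e-05, and adjusted p = 0.363 with an estimated correlation), with AOC3, of jasmonate synthesis, at -3.71 ± 0.14. Of 8 indole glucosinolate genes 6 fell (camera adjusted p = 2.75e-06, and adjusted p = 0.205 with an estimated correlation), with MYB51 at -2.15 ± 0.25. Of 14 cold and abscisic acid genes 3 fell, namely the cold regulators CBF1 (-2.36 ± 0.25) and CBF2 (-2.81 ± 0.28) and NCED3, of abscisic acid synthesis (-1.94 ± 0.23), and 2 rose, with COR15A at 2.1 ± 0.28. None of 13 endoplasmic reticulum chaperone genes and none of 12 leaf senescence genes passed.

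With limma, 2084 of 18328 genes passed, 472 higher and 1612 lower, 1363 of them at least 2-fold, and the simulated recovery was 51% and 98% for changes of 1 and 2 on the log2 scale. The count was 1243 without acd6-1 replicate 1, 1353 without acd6-1flk-1 replicate 2, and 3443 with the libraries of allele number 3 counted with number 1. Quantile normalization moved the median of all genes from 0.03 to 0.13 on the log2 scale, and 42.9% of 2762 called genes were higher rather than 22.6%. Against Col-0 the acd6-1flk-1 plants still differed in 8121 genes, 3896 higher and 4225 lower (4187 without acd6-1flk-1 replicate 1). Among them PR1 (5.30 ± 1.15, adjusted p = 0.0033), ICS1 (2.74 ± 0.56, adjusted p = 0.0024) and PR2, a glucanase gene of defence (3.94 ± 0.56, adjusted p = 0.00029), were higher, as were 25 of 26 pathogenesis-related and 23 of 27 salicylic acid genes. Of the 22 pattern-triggered immunity genes 14 were higher and 3 lower than in Col-0, PHI1 (-2.94 ± 0.20) and WRKY22 (-1.69 ± 0.19) among the latter. Of 13 chaperone genes 11 were higher, and of 30 photosynthesis genes 14 were lower, with a list median of -0.55 that became 0.051 under quantile normalization (camera adjusted p = 0.479).

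Of the 4934 genes higher in acd6-1 than in Col-0, 1407 were lower in acd6-1flk-1 than in acd6-1, and of the 4732 lower genes 389 were higher; 43 genes went further in the direction of acd6-1. Independent lists would share 434 and 122 genes, but both comparisons use the acd6-1 libraries, with the sign turned, so part of the excess may come from them. Over all genes 65.6% went opposite ways in the 2 comparisons, no more than the 68.5% that simulated groups without change gave, while the correlation with the sign turned was 0.693 against a simulated 0.547 and the covariance 0.480 against 0.0300. The 2373 genes at least 2-fold higher in acd6-1 lay a median of 1.62 above Col-0 in acd6-1, where they were chosen, 0.88 in acd6-1flk-1 and 1.27 in acd6-1flk-5, on the log2 scale. In the other groups the median was 1.63 in acd6-3, 0.82 in acd6-3flk-3, 1.21 in acd6-3flk-5, 0.42 in flk-5 and 0.06 in flk-1. All of these are differences from the Col-0 mean that also served to choose the genes, which can raise every group. The 1713 genes at least 2-fold lower in acd6-1 lay at a median of -1.34 in acd6-1, -1.07 in acd6-1flk-1 and -0.96 in acd6-3flk-3, but at -1.36 in acd6-1flk-5 and -1.29 in acd6-3flk-5, where acd6-3 was at -1.31.

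**Figure D3:**
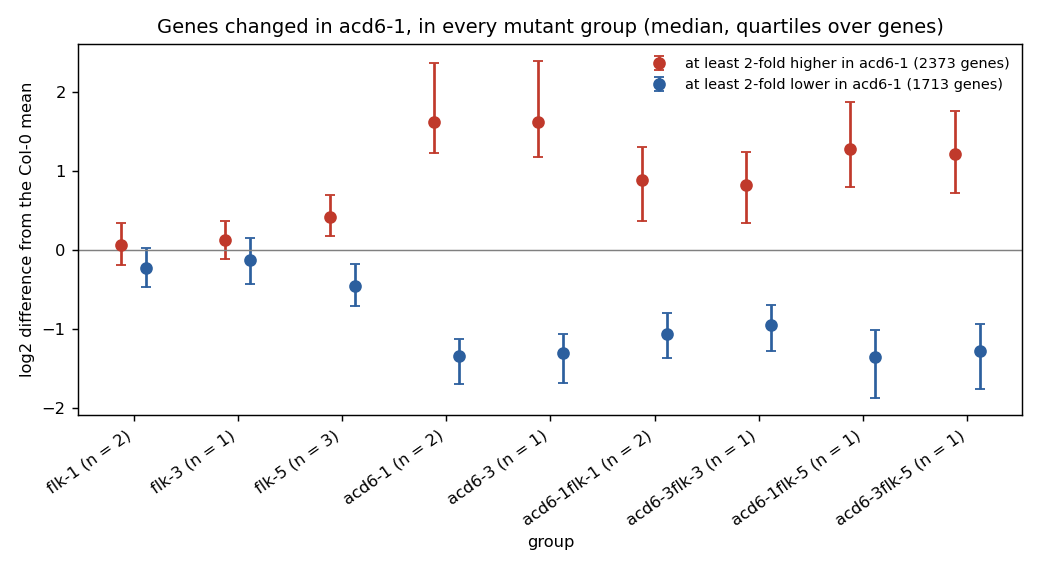
Median log2 difference from the Col-0 mean, with quartiles over genes as bars, of the 2373 genes at least 2-fold higher (red) and the 1713 at least 2-fold lower (blue) in acd6-1, in each mutant group. The higher genes lay at a median of 1.62 in acd6-1 and 0.88 in acd6-1flk-1, and the lower genes at -1.34 and -1.07, while in acd6-1flk-5 the higher genes lay at 1.27 and the lower ones at -1.36.

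The comparison of acd6-1flk-5 with acd6-1 put the other allele in the same background, with a single library. Its p-values, for genes and lists alike, rest on the assumption that this genotype varied as the other groups did, which no replicate of it could check. LOX4 fell by 4.1 ± 0.29 (adjusted p = 1.2e-05), PHI1 by 3.89 ± 0.27 (adjusted p = 1.2e-05) and XTH18, a xyloglucan enzyme gene, by 4.37 ± 0.29 (adjusted p = 1.1e-05). FLC rose by 3.02 ± 0.20 (adjusted p = 1.1e-05). PR1 was 2083 FPKM and ICS1 49.6 FPKM, and neither passed against acd6-1 (adjusted p = 0.97 and 0.87). Of 22 pattern-triggered immunity genes 16 fell and none rose (17 when adjusted over the list alone; median -1.42; camera adjusted p = 2.01e-18, and adjusted p = 0.0911 with an estimated correlation), with RBOHD at -3.0 ± 0.21 and PEPR1 at -2.67 ± 0.22. Of 27 salicylic acid genes 3 fell, with NPR3 at -1.55 ± 0.22, and the list's median was 0.03 (camera adjusted p = 0.806). Of 26 pathogenesis-related genes 1 rose and 1 fell. Of 33 jasmonate and ethylene genes 8 fell (camera adjusted p = 0.00383, adjusted p = 0.508 with an estimated correlation, and 0.0575 without acd6-1 replicate 2). The endoplasmic reticulum chaperone list moved up, with 1 of 13 genes past the threshold over all genes and 7 when adjusted over the list alone (median 0.81; camera adjusted p = 7.89e-07, and adjusted p = 0.495 with an estimated correlation). In all 1063 genes passed, 165 higher and 898 lower, and recovery of simulated changes was 34% and 90%. The count was 592 without acd6-1 replicate 1, 614 without acd6-1 replicate 2 and 2976 with the libraries of allele number 3 counted with number 1. The share higher was 15.5%, and 29.2% of 1316 genes under quantile normalization. Of the genes called in acd6-1flk-1 against acd6-1, 753 lower and 62 higher genes were also called in the same direction in acd6-1flk-5, where independent lists would share 79.0 and 4.25, and part of the excess may come from the shared acd6-1 libraries. Over all genes 64.8% went the same way, against 63.4% in simulated groups without change, and the correlation was 0.689 against 0.409 and the covariance 0.254 against 0.0301.

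The interaction term tested whether the flk-1 effect differed between the acd6-1 and Col-0 backgrounds. It passed in 1351 genes, 264 with a higher and 1087 with a lower flk-1 effect in acd6-1 than in Col-0. Listed genes with a lower flk-1 effect in acd6-1 included LOX4 (-6.03 ± 0.32, adjusted p = 4.6e-07), AOC3 (-4.53 ± 0.19, adjusted p = 1.1e-07), PHI1 (-4.64 ± 0.30, adjusted p = 1.2e-06) and RBOHD (-4.09 ± 0.23, adjusted p = 7.5e-07). Of 22 pattern-triggered immunity genes 14 had a lower flk-1 effect in acd6-1 and none a higher one (18 when adjusted over the list alone; camera adjusted p = 9.74e-19, and adjusted p = 0.0872 with an estimated correlation), and of 33 jasmonate and ethylene genes 12 had a lower effect and 1 a higher one. Of 27 salicylic acid genes 4 had a lower effect, NPR3 (-2.07 ± 0.24), NDR1 (-2.08 ± 0.30) and CBP60G (-2.80 ± 0.43) among them. PR1 did not pass (1.27 ± 1.71, adjusted p = 0.74). The count was 875 without acd6-1 replicate 1 and 2816 with the libraries of allele number 3 counted with number 1. Quantile normalization, which moved the median of all genes from 0.02 to 0.11, gave 38.7% of 1755 genes higher rather than 19.5%.

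**Figure D4:**
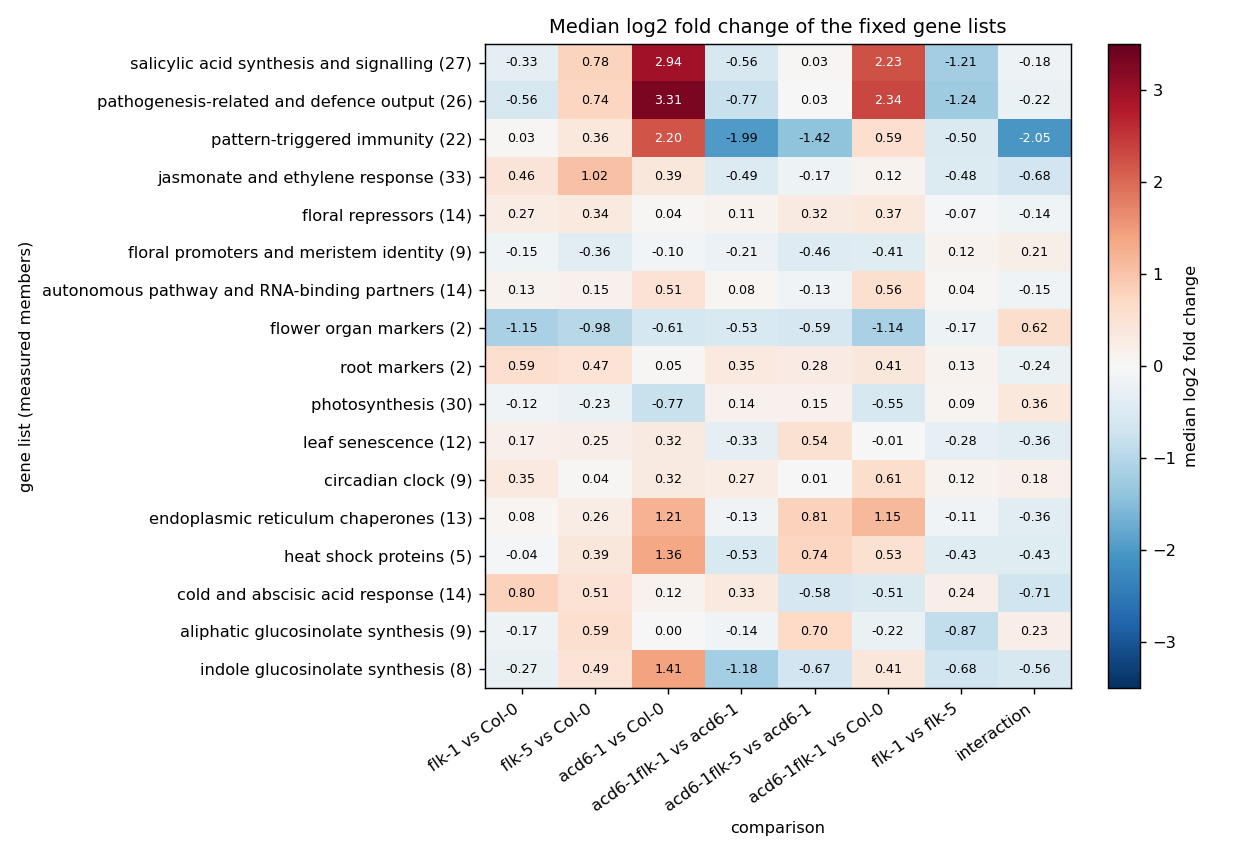
Median log2 fold change of the 17 fixed gene lists (number of measured members in brackets) in the 8 tested comparisons, with red for higher and blue for lower in the group named first. The pattern-triggered immunity list stood at 2.2 in acd6-1 against Col-0 and at -1.99 and -1.42 in acd6-1flk-1 and acd6-1flk-5 against acd6-1, and the photosynthesis list's medians against Col-0 in flk-5, acd6-1 and acd6-1flk-1 became 0.16, -0.035 and 0.051 under quantile normalization.

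The libraries labelled with allele number 3, each a single library of replicate 3, were set against the Col-0 or acd6-3 library of replicate 3 as values without a test. In flk-3, FLC stood at 26.0 FPKM against 1.24 FPKM and FLK at 1.32 against 9.55 FPKM. PR1 was 18.3 against 12.7 FPKM and ACD6 49.3 against 34.6 FPKM, and the pathogenesis-related list had a median of 0.43 (percentile 99.98). In flk-1 against the mean of all Col-0 libraries the list's median was -0.56. The references differ, since Col-0 replicate 3 had the lowest PR1 and ACD6 of the Col-0 libraries. Against the Col-0 mean of 24.9 FPKM, PR1 was lower in flk-3 as well as in flk-1 (5.17 FPKM). The flk-3 value lay within the range of the Col-0 libraries, 12.7 to 34.1 FPKM. The flk-1 libraries, at 2.77 and 7.57 FPKM, lay below that range. ACD6 in flk-3 was above the Col-0 mean of 44.2 FPKM but within the range of the Col-0 libraries, 34.6 to 49.9 FPKM. Random lists do not keep the correlation between the genes of a list, which limits the percentiles. In acd6-3, PR1 was 1154 FPKM against 12.7 FPKM in Col-0, and the median of the salicylic acid list was 3.30 higher on the log2 scale, above all 10000 random lists matched on mean expression (percentile 100). In acd6-3flk-3, PR1 was 706 FPKM, ICS1 was 21.2 FPKM against 91.2 FPKM in acd6-3, and the pattern-triggered immunity list had a median of -2.2 (percentile 0). In acd6-3flk-5, PR1 was 1903 FPKM and ICS1 45.7 FPKM. Against acd6-3 the pattern-triggered immunity list of this library had a median of -1.37 (percentile 0). The chaperone list stood at 0.72 (percentile 100) and the heat shock list at 0.15 (percentile 80.6). In acd6-1flk-5 against acd6-1 the medians of these 3 lists were -1.42, 0.81 and 0.74. The deposited sample sheet gives flk-3, acd6-3 and acd6-3flk-3 the genotype codes of flk-1, acd6-1 and acd6-1flk-1, and whether they carry other alleles is not settled by the labels.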

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

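The tests of library number, of flk-5 replicate 3 alone and of other groupings for the flk-5 count were chosen before their results were seen, and those for flk-5 replicate 3 and for the labels with allele number 3 afterwards.

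The flk-1 effect differed between the acd6-1 and Col-0 backgrounds by a test of the difference itself, the interaction term. It did so in 1351 genes. FLC was among them with -0.80 (adjusted p = 0.049), a call lost under quantile normalization (0.21), with voom on recovered reads (0.38, the highest of all settings) and in 7 of the fits with 1 library left out (up to 0.23, without acd6-1flk-1 replicate 1). The same test set apart the lists of pattern-triggered immunity (median difference -2.05), jasmonate and ethylene (-0.68), cold and abscisic acid (-0.71) and indole glucosinolate genes (-0.56). With an estimated correlation none of these passed (adjusted p = 0.0872, 0.314, 0.748 and 0.475), and at the preset correlation the cold and abscisic acid list did not pass without flk-1 replicate 2 (0.0709) or acd6-1 replicate 2 (0.141).

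In flk-5 replicate 3, PR1 and ICS1 mRNA lay far above the other flk-5 libraries. A wrong label was argued against, since its FLC was 1.11 times the mean of the others and its closest libraries were flk-5 replicates 1 and 2 (correlations 0.983 and 0.978). RNA mixed in from an acd6-1-background library cannot be told apart from a true rise, for which no biological explanation was tested. In a first test, as few as 14.9% of the genes at least 8-fold higher in the source implied under 0.5 of the median share, with 4 of 6 sources below the bound of 25%, whereas in a second, added because the first did not use each gene's error, at least 34.1% excluded a common share and 0 of 6 sources fell below the bound. Made mixtures with 25% of a source gave 0% in the first test and 1.06% to 7.14% in the second. This library gave 14.9% to 30% and 34.1% to 69.0%. The mixtures held the same source values from which the share was then computed, which by itself keeps their percentages low. They were also made at 1 share, whereas the best common share of this library was 3% to 23.5%, depending on the source. The contrast therefore does not decide for or against a mixed-in source.

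More genes were called for flk-5 (2992) than for flk-1 (368), which the 2 alleles themselves could bring about. A difference in library number as the whole account was argued against, as the lowest flk-5 count with 1 flk-5 library left out was 1216. So was flk-5 replicate 3 alone, as the count without it was also 1216. The flk-1 count itself went from 33 to 1453 with 1 library left out, which limits both tests. With allele number 3 counted with number 1, flk-1 had as many libraries as flk-5. The counts of flk-1 and flk-5 were then 2114 and 4506, so library number may account for part of the gap. Merging groups also leaves more residual degrees of freedom, and the flk-5 count rose from 2992 though neither flk-5 nor Col-0 gained a library. The rise in flk-1 therefore cannot be put down to library number alone. Of 10 splits of the Col-0 and flk-5 libraries only the real one, 1 of 10, called as many genes, and the highest other count was 0. Every other split put both genotypes in both groups, which by itself keeps calls few, and no split held a flk-1 library. With 10 splits a share under 0.05 cannot be reached either. The splits therefore cannot decide whether a grouping by chance gave the larger flk-5 count.

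The libraries labelled with allele number 3 resembled the groups of number 1. All 4 of 4 correlated best with the number 1 group of the same composition, which fits numbers filled down in the labels. The deposited sample sheet goes the same way, as it codes flk-3, acd6-3 and acd6-3flk-3 as replicate 3 of flk-1, acd6-1 and acd6-1flk-1. It does not list acd6-3flk-5, but it holds a replicate 2 under the code of acd6-1flk-5, for which no library was analysed here. By mRNA levels a separate flk allele of similar effect cannot be told apart. FLK mRNA in flk-3 was 1.05 times that of the highest flk-1 library and FLC 0.789 times the flk-1 mean, and such an allele could give the same values.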

How the results depend on the processing

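The voom fit was added after the data were seen, and all other alternatives were set before. Of 576 results for named genes 369 passed the threshold and 236 did so in every setting, with 0 reversed; of 136 list results 59 passed, 37 in every setting, and 3 reversed. Scaling by median ratios changed no call of a named gene or list. It left the values nearly as they were: flk-1 against Col-0 had 368 calls and a median over all genes of -0.0122 with and without it. This setting was therefore hardly a check of the normalization. Where a value moved, the cause was not tested unless the setting itself removes genes or libraries. With no filter, calls were 184 (flk-1 against Col-0, 368 otherwise), 17 (flk-1 against flk-5, 88 otherwise) and 153 (overlap of flk-1 and flk-5, 288 otherwise). Without trend, flk-1 against flk-5 had 50 calls, and with voom 135. With allele number 3 counted as number 1, calls were 2114 (flk-1), 4506 (flk-5), 3443 (acd6-1flk-1 against acd6-1), 2976 (acd6-1flk-5), 563 (flk-1 against flk-5), 2816 (interaction) and 1558 (overlap). Changes of at least 1 on the log2 scale were 127 (flk-1), 539 (flk-5), 4086 (acd6-1), 1363 (acd6-1flk-1 against acd6-1), 2679 (acd6-1flk-1 against Col-0) and 68 (overlap). The salicylic acid list in the acd6-3 library, 3.30 otherwise, was 3.59 with a pseudocount of 0.1, 3.21 under quantile normalization and 3.59 with voom. Quantile normalization turned the photosynthesis list to 0.158 in flk-5 and 0.051 in acd6-1flk-1 against Col-0 and left it at -0.035 in acd6-1, where camera pointed up.

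Replicate numbers were not seen to pair the samples: of 21 pairs of the same number 4 had a correlation of deviations over 0.1 (-0.375 to 0.207). The check is weak. Where both groups held only replicates 1 and 2, the deviations mirror each other and both numbers give the same value. Groups of 1 library could not enter the check, so a pairing is not excluded. With the replicate block, calls were 113 (flk-1), 17 (flk-1 against flk-5) and 102 (overlap), and with the block and allele number 3 counted as number 1 they were 1924 (flk-1), 3340 (acd6-1flk-1 against acd6-1), 2693 (acd6-1flk-5), 506 (flk-1 against flk-5), 2622 (interaction) and 1422 (overlap).

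With 1 library left out, counts ranged from 33 to 1453 (flk-1), 1216 to 3916 (flk-5), 6561 to 9764 (acd6-1), 1243 to 1420 (acd6-1flk-1 against acd6-1), 592 to 614 (acd6-1flk-5), 4187 to 8369 (acd6-1flk-1 against Col-0), 8 to 217 (flk-1 against flk-5), 875 to 1555 (interaction) and 25 to 1164 (overlap); the cold and abscisic acid list in flk-1 against Col-0 had a median of 0.63 without Col-0 replicate 1, and a group left with 1 library was assumed to vary like the others. The only acd6-1flk-5 library could not be left out. Count-table tools were not run, and camera was not run for the robust fit or the minimum change. Genes near an FPKM of 1 are those that depth limits most.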

Other observations

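All tests in this part were chosen after the data were seen, and domains were tested over 174 protein domains with at least 10 measured genes.

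Of 75 genes with a TIR domain, found in intracellular immune receptors, 70 rose and 1 fell in acd6-1 against Col-0 (median 1.70; camera adjusted p = 4.22e-21, and adjusted p = 0.716 with an estimated correlation). In acd6-1flk-1 against acd6-1, 41 of them fell and none rose, and in acd6-1flk-5 against acd6-1 23 fell and none rose. Of 57 WRKY transcription factor genes 41 rose and 1 fell in acd6-1, and in flk-5 15 rose and 2 fell. Of 40 genes with the auxin-inducible domain of SAUR proteins 25 fell and 4 rose in acd6-1 (median -1.21; camera adjusted p = 1.8e-06, and adjusted p = 0.716 with an estimated correlation), and in acd6-1flk-1 against acd6-1 16 rose and 5 fell. Close copies among these families make the share of each single gene uncertain.

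Compared directly, acd6-1flk-1 and the single acd6-1flk-5 library differed in 524 genes, 235 higher and 289 lower in acd6-1flk-1, but in 317 without acd6-1flk-1 replicate 1, 168 without acd6-1flk-1 replicate 2, 925 under quantile normalization and 2086 with allele number 3 counted as number 1. The single library was assumed to vary like the other groups, so the values below describe that library and do not settle a difference between the genotypes. The auxin response genes IAA29 (3.01 ± 0.29, adjusted p = 0.00036) and IAA19 were higher in acd6-1flk-1, and AOC3 was lower (-2.03 ± 0.17, adjusted p = 0.00023). Of 13 endoplasmic reticulum chaperone genes 2 were lower and none higher (median -0.995; camera adjusted p = 1.73e-09, and adjusted p = 0.384 with an estimated correlation). Of 5 heat shock genes 3 were lower (median -1.50; camera adjusted p = 1.39e-06, and adjusted p = 0.259 with an estimated correlation). The salicylic acid list (1 of 27 lower, median -0.76), the pathogenesis-related list (0 of 26, -0.91) and the pattern-triggered immunity list (0 of 22, -0.48) were also called lower by camera (adjusted p = 3.95e-06, 8.38e-05 and 0.000364), though with an estimated correlation adjusted p was 0.501, 0.522 and 0.479. PR1 did not pass (-1.14 ± 1.54, adjusted p = 0.84).

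QQS and PI4KG3 mRNA was high in the flk-5 and acd6 lines and low in Col-0 and the flk-1 lines, acd6-1flk-1 included. A level inherited with lines that share an acd6-1 parent is a hypothesis only, as no label gives the parentage of flk-5. In its test the lowest QQS among the former libraries was 3.82 times the highest among the latter, which such a level and an effect of the mutations would both give, so they cannot be told apart. The libraries were grouped by this gene's level, so the ratio restates what was seen. QQS was 5.98 to 7.02 FPKM in acd6-1flk-1 and acd6-3flk-3, which goes against such a level in every line with an acd6 mutation.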
